A study of Mus musculus with 6 samples.

How the data were processed

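Poly(A) RNA of RAW 264.7 cells was sequenced as paired ends on an Illumina NovaSeq instrument, per the labels, in 2 groups of 3 libraries. The deposited values are FPKM for 55335 mouse Ensembl gene identifiers, computed by the authors. The aligner, quantifier, annotation and mouse build are not given in the sources used here. The submitters' processing notes name a rat build, mRatBN7.2, and the extraction text describes rat muscle, while 55335 of 55335 identifiers are mouse ones and the cell line in the labels is a mouse macrophage line. The values were therefore read as mouse macrophage data, and the macrophage and muscle markers in the report bear on this. Because the mouse build is not named, no coordinates are given. The GENCODE M21 annotation was used only for names, overlaps, lengths and neighbours, and 55154 identifiers had a symbol. Columns were assigned to libraries by the initial and number they share with the sample titles.

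The table holds no counts. For genes with 1 annotated transcript, low values multiplied by transcript length piled up at steps, which would mean 25300000 to 29300000 fragments per library if 1 step were 1 fragment, a ratio of 1.16 between the highest and lowest. Not all values are multiples of the steps, so no counts were recovered and no interval for counting error is given. The FPKM sums were 278870 to 292200 per library, and 11128 to 11299 genes had 1 FPKM or more. Among the genes, 10 were listed at 0 in one library and above 5 FPKM in another, so an exact 0 can be a failed estimate. FPKM is relative to the sum of the library, so a few abundant genes that move shift all others, and reads of overlapping genes or near-identical copies can be divided between them in ways the table does not show.

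Genes with a mean of at least 1 FPKM over the 6 libraries were tested, which left 11270 and removed 44065. Groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and robust moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 26 gene lists were tested with camera at the preset correlation 0.01, adjusted over the lists with at least 5 measured members, beside camera with an estimated correlation and fry. The estimated correlations of the 10 called lists ran from 0.07 to 0.85, above the preset value. With the estimated correlation 0 of the 10 called lists passed, and fry, which asks whether a list's genes move without comparing them with other genes, passed 0 lists for a shared direction and 2, the mitochondrial and NRF2 lists, for change in either direction. A list is said below to rise or fall where camera at the preset correlation called it. The groups share the replicate numbers 1, 2 and 3 in their titles. The correlations of deviations from the group means between same-numbered libraries were 0.18, 0.44 and 0.41, taken across genes, and those between differently numbered libraries -0.40 to 0.06. The deviations of a group sum to 0, so these lower values are not separate evidence. The numbers were taken to pair the libraries, from the data and the titles, so the pairing rests in part on the values that the block uses. The fit without a block stayed the main one because it was fixed before the data were examined.

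The lists, the cell type markers, the design, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 largest changes per direction among genes past the threshold with separate groups, a mean of at least 5 FPKM in the higher group and a symbol that is not provisional. Where no gene passed in a direction it took the 10 smallest p among genes that met the other conditions. It added up to 3 members with the smallest p from each list that camera called or that had at least 3 members past the threshold, 10 genes named in advance and the up to 3 highest markers of each cell type. Some genes that the rule names are not reported here. Alternatives were the pseudocount, the filter, 3 scalings, the moderation, sample weights, the threshold, the replicate block and leaving out each library. Leaving out both libraries numbered 2, and 2 gene list tests with the block, were added after the data were seen.

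The gene and list tests were tested on simulated data for LPS plus ultrasound against LPS with 11270 genes, of which 200 were changed. Of 50 genes per size, 48% were recovered at 1.5-fold, 78% at 2-fold, 96% at 3-fold and 100% at 4-fold, with 10 false calls. With no gene changed there were 0 calls, and a list shifted by 0.3 on the log2 scale was called with 0 others. The simulated genes were drawn independently of each other and without pairs of libraries. The simulation therefore cannot show how often lists of correlated genes are called falsely. The adjusted threshold is easier to pass with 200 changed genes than with few, and in the real data 2 genes passed. The recovered shares can therefore overstate what the real comparison would detect. Annotation and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.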

Results

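RNA was measured in RAW 264.7 cells, a mouse macrophage line, after stimulation with lipopolysaccharide (LPS), a bacterial cell wall component that acts through TLR4 and starts an inflammatory response. All cells received 200 ng/ml LPS for 8 h. In 3 libraries LPS was the only treatment. In the other 3 libraries the cells also received low-intensity pulsed ultrasound for 10 min within that period, at 50 mW/cm² and 1 MHz, with a 20% duty cycle, a pulse repetition frequency of 1 kHz and pulses of 200 µs. The design gives 1 comparison, LPS plus ultrasound against LPS, which asks how ultrasound alters the transcriptome of LPS-stimulated macrophages. Cells without LPS were not analysed here, so the response to LPS itself was not measured. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Values are FPKM, a fragment density scaled to transcript length and to the mapped fragments of the library, given as mean ± SD with n = 3 per group. Fold changes are differences of log2(FPKM + 1), LPS plus ultrasound minus LPS, ± the standard error, and this scale understates the change of low genes.

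The libraries carried a macrophage profile. All 11 macrophage markers had a mean of at least 1 FPKM, led by the Fc receptor subunit gene Fcer1g at 902 ± 68.3 FPKM with LPS and 896 ± 63.5 with ultrasound. The lysosomal glycoprotein gene Cd68 lay at 645 ± 35.1 and 668 ± 30.3 FPKM and Laptm5 at 296 ± 46.5 and 355 ± 35.9. None of the 14 skeletal muscle, 8 fibroblast, 6 tendon cell, 6 endothelial, 6 erythroid, 6 neutrophil, 6 T cell, 5 B cell and 3 muscle stem cell markers reached a mean of 1 FPKM. The highest of the muscle markers, Mylpf, had a mean of 0.587 FPKM over the 6 libraries, and the highest tendon marker, Scx, 0.566. Of 5 adipocyte markers only Fabp4 passed 1 FPKM, at 1.73 ± 0.388 and 1.45 ± 0.412. Of 5 dendritic cell markers only Itgax did, at 8.64 ± 1.41 and 10.95 ± 1.78.

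LPS library 2 stood apart from the other 5 libraries. Principal component 1 held 41.9% of the variance of the tested genes and placed LPS library 2 at 28.8, against 1.73 and 2.03 for LPS libraries 1 and 3 and -17.7 to -0.957 for the ultrasound libraries. Pearson correlations between libraries, taken across genes, which are not independent replicates, ran from 0.962 to 0.989. Of the 61 tested members of the cytokine, chemokine, interferon and effector lists described below, 53 were highest in library 2 among the LPS libraries and 48 in library 2 among the ultrasound libraries.

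**Figure D1:**
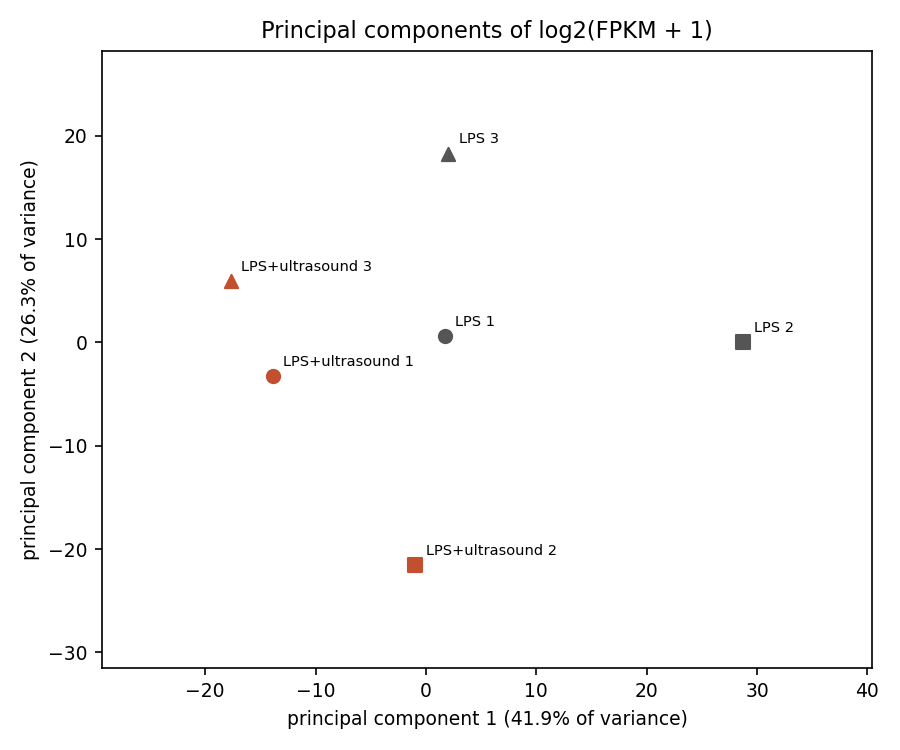
Principal components 1 and 2 of log2(FPKM + 1) over the 11270 tested genes, with the share of variance on each axis and 1 point per library (grey LPS, orange LPS plus ultrasound). LPS library 2 lies at 28.8 on component 1, and the ultrasound libraries lie between -17.7 and -0.957.

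Ultrasound was followed by higher Krcc1 and Mir8112, the only genes past the threshold. Krcc1 (ENSMUSG00000053012), a gene for a lysine-rich coiled-coil protein, rose 3.68-fold from 4.48 ± 0.0996 to 16.5 ± 1.48 FPKM (log2 fold change 1.67 ± 0.09, limma with Benjamini-Hochberg adjusted p = 0.0012). Mir8112 (ENSMUSG00000098623), an annotated microRNA precursor, rose from 0.0173 ± 0.0146 to 5.61 ± 0.599 FPKM (log2 fold change 2.70 ± 0.10, limma with Benjamini-Hochberg adjusted p = 0.00023). Every ultrasound library lay above every LPS library for both genes. In the GENCODE M21 annotation, 125 of the 131 bases of Mir8112 lie in exons of Krcc1 on the same strand, so the 2 features share sequence and their calls are not independent. Reads in the shared bases cannot be told apart, so a rise of the microRNA precursor itself was not shown. The LPS values of Mir8112 also lie far below the 1 FPKM used as the filter, so the size of its change is uncertain. The annotated Krcc1 transcripts run from 417 to 1749 bases, so the FPKM also depends on the isoform to which reads were assigned.

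Across the 11270 tested genes, 2 were higher and 0 were lower at a Benjamini-Hochberg adjusted limma p below 0.05. At an unadjusted limma p below 0.05, 697 were higher and 1032 lower, where 564 in all are given by chance. Other splits of the 6 libraries into groups of 3 gave 101 to 1678 such genes, so 564 is not a bound. The groups were separate, with all 3 libraries of one above all 3 of the other, for 2614 genes (23.2%, against 10% by chance). With the replicate number as a block, limma placed 4 genes higher and 9 lower past the threshold, and 223 genes passed with sample weights, 71 higher and 152 lower. Scaling each library to the same sum moved the share of higher genes among those with an unadjusted p below 0.05 from 40.3% to 29.9%, and median-ratio scaling and quantile normalization moved it to 48.7% and 48.6%.

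The 10 lower genes with the smallest p that met the other conditions of the naming rule did not pass the threshold (limma with Benjamini-Hochberg adjustment, 0.061 to 0.13). The rule took no such genes in the higher direction, where genes had passed. Paqr7, a membrane progesterone receptor gene, had 5.72 ± 0.737 FPKM with LPS and 2.28 ± 0.238 with ultrasound (log2 fold change -1.03 ± 0.11), and the signalling adaptor gene Crk had 35.3 ± 6.85 and 15.6 ± 1.00 (-1.11 ± 0.14). The chemokine receptor-like gene Ccrl2 had 46.5 ± 14.7 and 18.7 ± 1.73 FPKM (-1.23 ± 0.20). The mitotic genes Bub1b, a spindle checkpoint kinase gene, and Cenpa, the centromeric histone gene, had log2 fold changes of -0.73 ± 0.10 and -0.57 ± 0.09. The transcription factor gene Stat5a (-0.60 ± 0.09), the aldehyde dehydrogenase gene Aldh1b1 (-0.66 ± 0.10), the adaptor complex gene Ap5s1 (-0.74 ± 0.11), the aquaporin gene Aqp9 (-0.54 ± 0.09) and Ly6e (-0.57 ± 0.09) complete the 10.

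Passing the threshold with the replicate block was not part of the naming rule. Of the genes given here, Paqr7, Crk, Stat5a and, as a chemokine list member, Ccl4 come under that rule anyway. The others were chosen after their values were seen. Ppard, a lipid-sensing nuclear receptor gene, rose in that fit from 11.2 ± 0.641 to 19.9 ± 1.41 FPKM (limma with Benjamini-Hochberg adjusted p = 0.035 with the block and 0.061 without), and the transcriptional co-regulator gene Nab1 from 26.4 ± 2.24 to 42.6 ± 3.49 (0.047 and 0.13). The chemokine genes Ccl4 and Ccl5 fell in it, from 310 ± 228 to 124 ± 86.5 FPKM and from 318 ± 195 to 175 ± 102 (limma with Benjamini-Hochberg adjusted p = 0.023 and 0.035 with the block, 0.37 and 0.45 without). The interferon-induced gene Ifit1 fell from 14.0 ± 9.19 to 6.67 ± 4.98 FPKM and the viral RNA sensor gene Ifih1 from 21.5 ± 5.72 to 13.4 ± 3.58 (limma with Benjamini-Hochberg adjusted p = 0.035 and 0.047 with the block, 0.43 and 0.26 without). Leaving out LPS library 2 moved the log2 fold changes of Ccl4, Ccl5 and Ifit1 from -1.29, -0.84 and -0.98 to -0.73, -0.37 and -0.52, and leaving out both libraries numbered 2 to -1.25, -0.82 and -1.01. Paqr7, Crk, Stat5a, the kinase gene Pim2 and Txnip, whose product binds thioredoxin, also fell with the block (limma with Benjamini-Hochberg adjusted p = 0.035 for Paqr7 and 0.047 for the others).

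Inflammatory cytokine genes were lower with ultrasound in 14 of 15 measured members, with a median log2 fold change of -0.66. As a list they fell (camera with Benjamini-Hochberg adjusted p = 1.4e-05), with adjusted p = 0.65 with an estimated correlation. Over all genes tested 0 members passed limma's threshold, and adjusted over the list alone 6 did, or 12 with the replicate block. Il23a, a subunit gene of interleukin-23, had 20.3 ± 0.442 FPKM with LPS and 13.5 ± 1.69 with ultrasound (log2 fold change -0.57 ± 0.10). The costimulatory ligand gene Tnfsf9 had 61.7 ± 16.8 and 38.4 ± 1.78 FPKM (-0.64 ± 0.17), and Il27 4.88 ± 2.29 and 1.99 ± 0.378 (-0.92 ± 0.26). The classical LPS-induced genes did not pass over all genes tested: Tnf had 128 ± 76.3 and 67.4 ± 11.5 FPKM, Il1b 17.7 ± 16.3 and 4.70 ± 2.47, and Il6 5.26 ± 3.58 and 3.06 ± 2.58 (log2 fold changes -0.77 ± 0.38, -1.42 ± 0.62 and -0.66 ± 0.51, limma with Benjamini-Hochberg adjusted p = 0.39, 0.34 and 0.55, and 0.16, 0.091 and 0.058 with the replicate block). Each of these genes was lower with ultrasound in 3 of 3 same-numbered pairs. Leaving out LPS library 2 moved their log2 fold changes to -0.32, -0.74 and -0.22, and leaving out both libraries numbered 2 to -0.45, -1.08 and -0.71. With the block and adjusted over the list alone, Il1b and Il6 passed and Tnf did not (limma with Benjamini-Hochberg adjusted p = 0.019, 0.0040 and 0.052). Without LPS library 2 the median of the list was -0.47 and the list was still called by camera (Benjamini-Hochberg adjusted p = 4.3e-06).

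**Figure D2:**
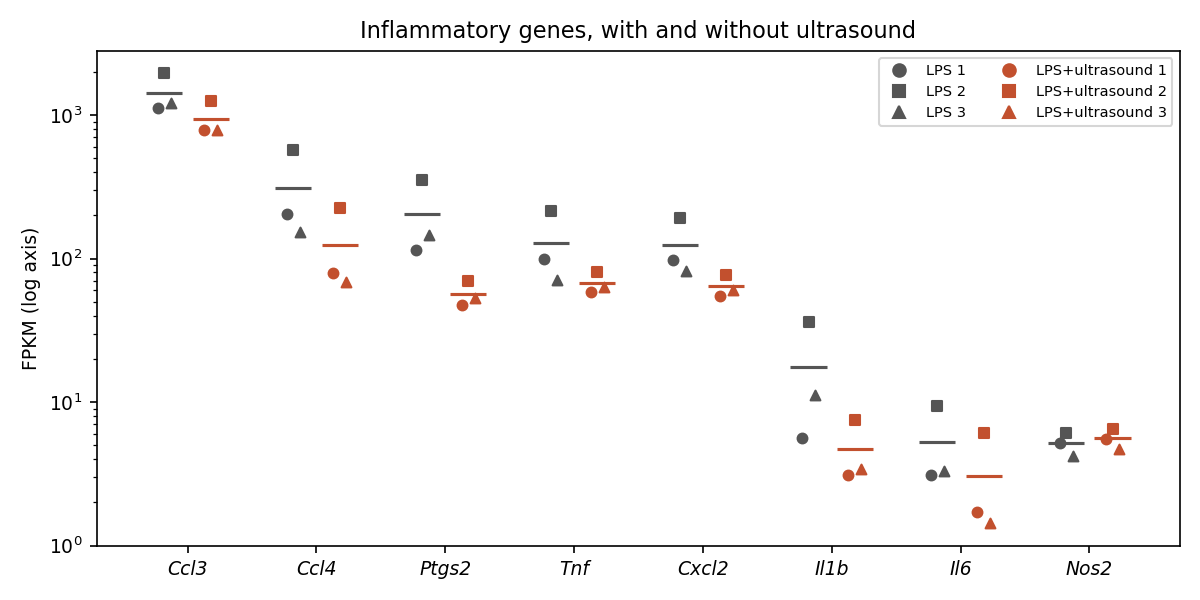
FPKM on a log axis of 8 inflammatory genes in each library (grey LPS, orange LPS plus ultrasound, symbol shape for the replicate number, horizontal lines for the mean of 3). Ptgs2 lies between 114 and 354 FPKM in the LPS libraries and between 47.6 and 69.9 in the ultrasound libraries, while Nos2 overlaps.

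Chemokine genes were lower in 9 of 9 measured members, with a median log2 fold change of -0.33, and the list fell (camera with Benjamini-Hochberg adjusted p = 0.026), with adjusted p = 0.65 with an estimated correlation. In limma 0 members passed adjusted over the list alone and 0 over all genes tested, while with the replicate block 5 passed over the list alone and 2, Ccl4 and Ccl5, over all genes. The neutrophil-attracting chemokine gene Cxcl2 had 124 ± 59.8 FPKM with LPS and 64.1 ± 11.3 with ultrasound (log2 fold change -0.86 ± 0.30), and Ccl3 1432 ± 456 and 940 ± 264 (-0.60 ± 0.26). These became -0.50 and -0.35 without LPS library 2, and -0.63 and -0.57 without both libraries numbered 2. The call ended without LPS library 2 (median -0.18, camera with Benjamini-Hochberg adjusted p = 0.36) and without ultrasound library 1 (-0.30, adjusted p = 0.12), and held without both libraries numbered 2 (-0.26, adjusted p = 0.0042).

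Interferon response genes were lower in 23 of 24 measured members, with a median log2 fold change of -0.42, and the list fell (camera with Benjamini-Hochberg adjusted p = 1.0e-04), with adjusted p = 0.65 with an estimated correlation. Gene by gene, limma passed 1 member adjusted over the list alone and 0 over all genes tested, against 21 and 2 with the replicate block. Bst2, the antiviral tethering factor gene, had 318 ± 28.0 FPKM with LPS and 236 ± 9.21 with ultrasound (log2 fold change -0.43 ± 0.08). Zbp1, a nucleic acid sensor gene, had 8.34 ± 4.05 and 3.55 ± 0.712 FPKM (-0.97 ± 0.28), and Mx2 7.12 ± 1.43 and 4.96 ± 0.115 (-0.43 ± 0.13). Zbp1 moved to -0.63 without LPS library 2 and to -0.76 without both libraries numbered 2. The median moved to -0.16 without LPS library 2 (camera with Benjamini-Hochberg adjusted p = 0.040) and to -0.34 without both libraries numbered 2 (adjusted p = 6.5e-08).

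Inflammatory effector enzymes and receptors were lower in 11 of 13 measured members, with a median log2 fold change of -0.40, and the list fell (camera with Benjamini-Hochberg adjusted p = 0.022), with adjusted p = 0.65 with an estimated correlation. Adjusted over the list alone 3 members passed limma's threshold and 0 over all genes tested, and with the replicate block 7 passed over the list alone. Ptgs2, the inducible cyclooxygenase gene, had 205 ± 130 FPKM with LPS and 56.8 ± 11.7 with ultrasound (log2 fold change -1.67 ± 0.41). The NADPH oxidase subunit genes Cybb and Ncf1 had 182 ± 30.4 and 121 ± 15.7 FPKM (-0.59 ± 0.14) and 57.8 ± 12.5 and 38.2 ± 3.60 (-0.57 ± 0.16). Nos2, the inducible nitric oxide synthase gene, had 5.14 ± 0.920 and 5.59 ± 0.882 FPKM, which differed by less than the spread between the libraries of a group. It was slightly higher with ultrasound in each same-numbered pair and did not pass (limma with Benjamini-Hochberg adjusted p = 0.75, and 0.30 with the replicate block). The call ended without LPS library 2 (median -0.02, camera with Benjamini-Hochberg adjusted p = 0.16) and without ultrasound library 1 (-0.17, adjusted p = 0.071). It held without both libraries numbered 2, at a median of -0.25 (camera with Benjamini-Hochberg adjusted p = 0.0084).

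Mitochondrially encoded genes were higher in 12 of 13 members, with a median log2 fold change of 0.82. The list rose (camera with Benjamini-Hochberg adjusted p = 5.1e-07), with adjusted p = 0.65 with an estimated correlation. Of the members, 7 passed limma's threshold adjusted over the list alone and 0 over all genes tested. mt-Co2, a cytochrome c oxidase subunit gene, had 417 ± 53.1 FPKM with LPS and 1137 ± 224 with ultrasound (log2 fold change 1.43 ± 0.15). The ATP synthase subunit gene mt-Atp8 had 821 ± 79.1 and 1452 ± 175 FPKM (0.82 ± 0.11), and the complex I subunit gene mt-Nd3 28.3 ± 10.7 and 93.5 ± 3.33 (1.77 ± 0.27). The most abundant member, mt-Co1, had 9634 ± 1131 and 8436 ± 446 FPKM (-0.19 ± 0.11). The log2 fold changes of mt-Nd5 and mt-Nd6 were 0.12 ± 0.21 and 0.04 ± 0.21, which turned to -0.09 and -0.14 without LPS library 2. Those of mt-Nd4 and mt-Nd4l moved from 0.37 and 0.40 to 0.10 and 0.13 without that library, while mt-Co2 stayed at 1.38 and mt-Co3 at 0.59. Reads of several members are shared with nuclear copies, so single values are uncertain. LPS library 2 was the lowest of the 6 libraries for 11 of the members, and without it the median was 0.63 (camera with Benjamini-Hochberg adjusted p = 2.4e-09).

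**Figure D3:**
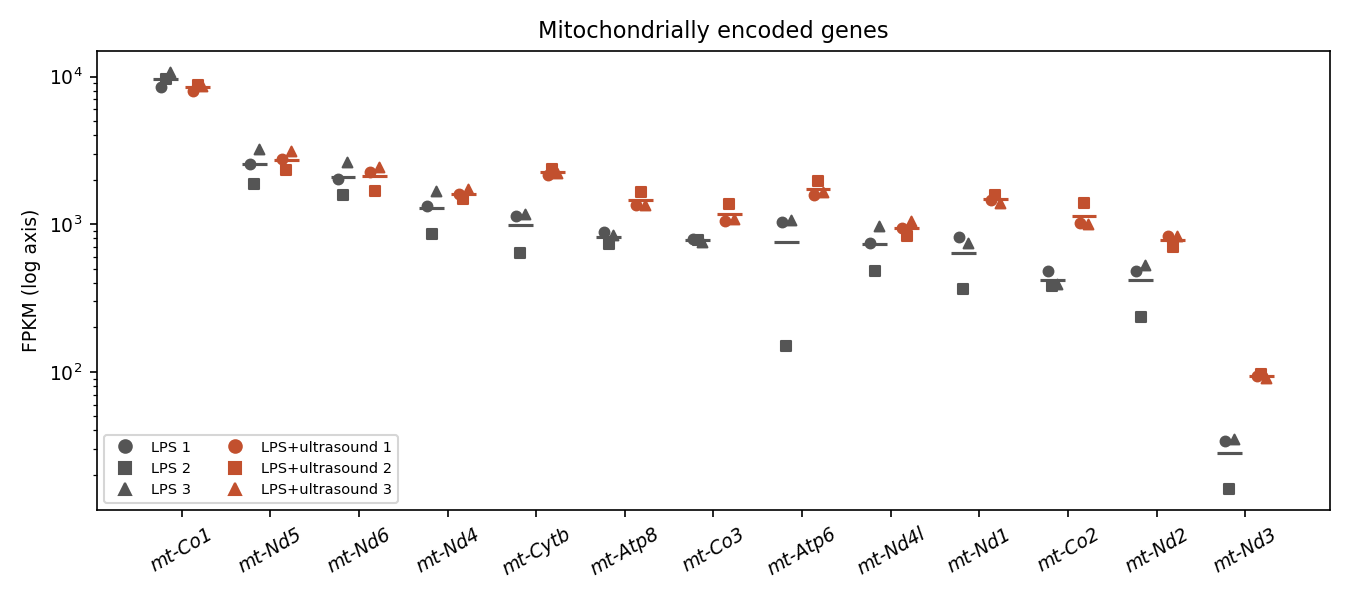
FPKM on a log axis of the 13 mitochondrially encoded genes in each library (grey LPS, orange LPS plus ultrasound, symbol shape for the replicate number, horizontal lines for the mean of 3). mt-Nd3 lies between 16.0 and 34.9 FPKM in the LPS libraries and between 90.5 and 97.1 in the ultrasound libraries, while mt-Co1 and mt-Nd5 overlap.

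NRF2 and antioxidant genes were higher in 17 of 18 measured members, with a median log2 fold change of 0.26, and the list rose (camera with Benjamini-Hochberg adjusted p = 1.0e-05), with adjusted p = 0.61 with an estimated correlation. In limma 6 members passed adjusted over the list alone, or 11 with the replicate block, and 0 over all genes tested. Srxn1, the sulfiredoxin gene, had 46.9 ± 15.0 FPKM with LPS and 100.1 ± 7.13 with ultrasound (log2 fold change 1.13 ± 0.23). The pentose phosphate pathway genes Pgd and G6pdx, which supply NADPH, had 41.7 ± 2.17 and 65.8 ± 10.1 FPKM (0.64 ± 0.11) and 77.3 ± 1.02 and 95.3 ± 6.07 (0.30 ± 0.07). Hmox1, named after its value was seen because it is a widely used NRF2 target, had 49.2 ± 8.03 and 52.5 ± 5.50 FPKM. Without LPS library 2 the median was 0.25 (camera with Benjamini-Hochberg adjusted p = 1.8e-06).

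Cholesterol synthesis genes were higher in 12 of 17 members, with a median log2 fold change of 0.14, and the list rose (camera with Benjamini-Hochberg adjusted p = 0.020), with adjusted p = 0.65 with an estimated correlation. Adjusted over the list alone 1 member passed limma's threshold and 0 over all genes tested, and 0 passed over the list alone with the replicate block. Insig1, a sterol-regulated gene, had 30.6 ± 2.08 FPKM with LPS and 38.3 ± 2.70 with ultrasound (log2 fold change 0.31 ± 0.08). The call ended without both libraries numbered 2 (median 0.03, camera with Benjamini-Hochberg adjusted p = 0.34), without LPS library 1 (0.08, adjusted p = 0.19) and without ultrasound library 2, where the median turned to -0.05 (adjusted p = 0.76). It held without LPS library 2, at 0.21 (camera with Benjamini-Hochberg adjusted p = 0.0022).

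Cell cycle genes were lower in 20 of 21 measured members, with a median log2 fold change of -0.20, and the list fell (camera with Benjamini-Hochberg adjusted p = 0.0043), with adjusted p = 0.65 with an estimated correlation. Adjusted over the list alone 0 members passed limma's threshold and 0 over all genes tested, and with the replicate block 7 passed over the list alone. The G1/S cyclin gene Ccne1 had 8.73 ± 2.09 FPKM with LPS and 5.03 ± 0.760 with ultrasound (log2 fold change -0.67 ± 0.18). The checkpoint kinase gene Bub1 had 6.86 ± 1.61 and 4.29 ± 0.496 FPKM (-0.55 ± 0.16), and Mcm2, a replicative helicase gene, 8.18 ± 0.692 and 6.77 ± 0.259 (-0.24 ± 0.09). The list was not called without LPS library 2, at a median of -0.13 (camera with Benjamini-Hochberg adjusted p = 0.087), and was called without both libraries numbered 2, at -0.19 (adjusted p = 0.0066).

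Glycolysis genes were lower in 16 of 18 members, with a median log2 fold change of -0.15, and the list fell (camera with Benjamini-Hochberg adjusted p = 0.012), with adjusted p = 0.65 with an estimated correlation. Adjusted over the list alone 1 member passed limma's threshold and 0 over all genes tested, and with the replicate block 6 passed over the list alone. The phosphofructokinase genes Pfkl and Pfkp had 18.5 ± 3.30 FPKM with LPS against 10.97 ± 1.17 with ultrasound (log2 fold change -0.69 ± 0.14) and 45.5 ± 3.63 against 36.9 ± 2.85 (-0.29 ± 0.09). The glucose transporter gene Slc2a1 had 102 ± 16.4 and 77.4 ± 3.44 FPKM (-0.39 ± 0.12). Ribosomal protein genes were lower in 20 of 20 members, with a median log2 fold change of -0.10, and that list fell (camera with Benjamini-Hochberg adjusted p = 0.020), with adjusted p = 0.67 with an estimated correlation. Among ribosomal members 0 passed limma's threshold adjusted over the list alone and 0 over all genes tested. Rpl3 had 147 ± 23.1 and 116 ± 7.82 FPKM (-0.33 ± 0.12, and -0.20 without LPS library 2), Rpl7 285 ± 12.0 and 254 ± 5.80 (-0.17 ± 0.07) and Rpsa 445 ± 36.3 and 372 ± 46.3 (-0.26 ± 0.11), and reads of ribosomal protein genes can be shared with their pseudogenes. Neither list was called without LPS library 2 (medians -0.12 for glycolysis and -0.05 for ribosomal proteins, camera with Benjamini-Hochberg adjusted p = 0.084 and 0.34) or without ultrasound library 1 (-0.11 and -0.09, adjusted p = 0.071 for both). The glycolysis list was called without both libraries numbered 2 (-0.11, camera with Benjamini-Hochberg adjusted p = 0.0094), as were 8 of the 10 called lists in all. The ribosomal list was not called either without ultrasound library 3 (-0.09) or without both libraries numbered 2 (-0.06, camera with Benjamini-Hochberg adjusted p = 0.073 and 0.11).

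**Figure D4:**
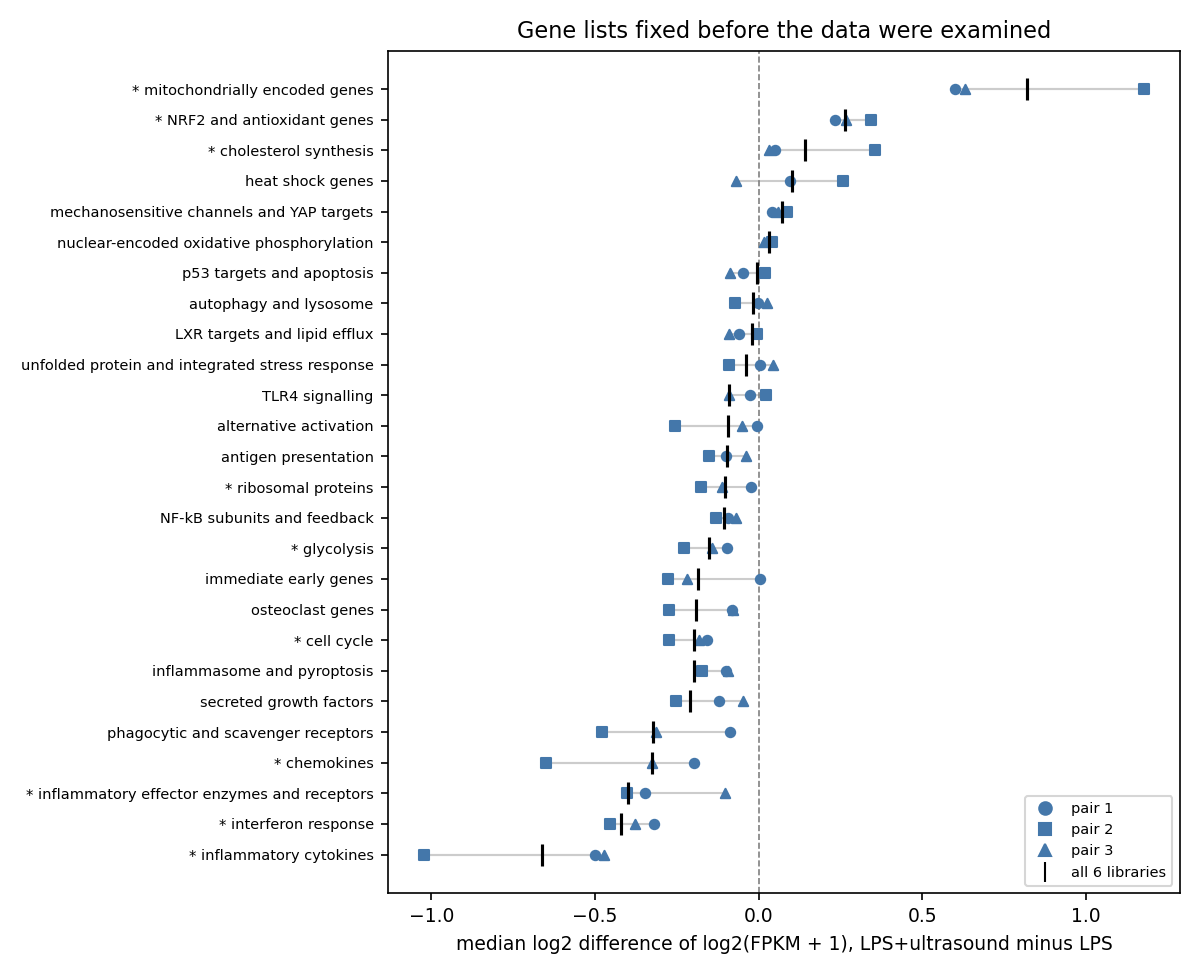
Median log2 difference over the members of each of the 26 gene lists, LPS plus ultrasound minus LPS, for all 6 libraries (black bar) and within each same-numbered pair (blue symbols). Asterisks mark the 10 lists called by camera with the preset correlation. The cytokine list lies at -0.50, -1.02 and -0.47 in pairs 1, 2 and 3, and the mitochondrial list at 0.60, 1.18 and 0.63.

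The other 16 lists were not called (camera with Benjamini-Hochberg adjusted p between 0.071 and 0.95). The NF-kB subunits and feedback list came closest, with 11 of 16 members lower and a median log2 fold change of -0.11 (camera with Benjamini-Hochberg adjusted p = 0.071), and it was called without ultrasound library 3 (-0.13, adjusted p = 0.011). Mechanosensitive channels and YAP targets had 6 measured members with a median of 0.07 (camera with Benjamini-Hochberg adjusted p = 0.44), and Piezo1, a stretch-activated channel gene, had 49.0 ± 3.72 and 53.3 ± 2.56 FPKM. Heat shock genes had 9 of 13 members higher and a median of 0.10 (camera with Benjamini-Hochberg adjusted p = 0.44, and 0.026 with a median of 0.26 without LPS library 3), and Hspa1a lay below the filter at 0.391 ± 0.223 and 0.327 ± 0.0461 FPKM. In the alternative activation list 5 of 16 genes were measured, with a median of -0.09 (camera with Benjamini-Hochberg adjusted p = 0.44). Of that list, Arg1 had 0.464 ± 0.0836 and 0.515 ± 0.0433 FPKM, Mrc1 0.00435 ± 0.00378 and 0.0163 ± 0.00986, and Il10 0.479 ± 0.142 and 0.519 ± 0.195, all below the filter.

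Among the remaining lists, the medians and camera's Benjamini-Hochberg adjusted p were -0.32 and 0.16 for phagocytic and scavenger receptors, -0.10 and 0.22 for antigen presentation, -0.19 and 0.23 for immediate early genes and -0.20 and 0.34 for inflammasome and pyroptosis genes. They were -0.21 and 0.36 for secreted growth factors, -0.09 and 0.38 for TLR4 signalling, -0.02 and 0.38 for LXR targets and lipid efflux and -0.04 and 0.40 for the unfolded protein and integrated stress response (camera with Benjamini-Hochberg adjustment). Nuclear-encoded oxidative phosphorylation genes had 0.03 and 0.41, osteoclast genes -0.19 and 0.44, p53 targets and apoptosis genes -0.005 and 0.53, and autophagy and lysosome genes -0.02 and 0.95 (camera with Benjamini-Hochberg adjustment). Leaving out LPS library 1 gave a call of the phagocytic list (-0.40, camera with Benjamini-Hochberg adjusted p = 0.022) and leaving out ultrasound library 3 one of the immediate early list (-0.16, adjusted p = 0.043). Of these 16 lists, 0 had a member past limma's threshold over all genes tested. Adjusted over the list alone, 4 members passed in the p53 list, 3 in the TLR4 list, 2 in the unfolded protein list and 1 each in the NF-kB and immediate early lists, and 0 in the others. With the replicate block these were 3, 6, 3, 1 and 2, with 5 in the inflammasome and phagocytic lists, 4 in the antigen presentation and osteoclast lists, and 1 in the mechanosensitive and LXR lists. The block placed 1 inflammasome member, Txnip, past the threshold over all genes tested.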

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

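The tests without both libraries numbered 2, and those of the gene lists with the block under an estimated correlation or fry, were chosen after the data were seen. The counts of 2 higher and 0 lower genes became 1 higher with a mean FPKM of at least 5, 4 and 2 with each library scaled to the same sum, 71 and 152 with sample weights, 4 and 9 with the replicate block, 5 and 1 without pair 2, and 697 and 1032 at an unadjusted p below 0.05. Leaving out 1 library gave 2 to 6 higher and 0 to 2 lower genes, with the most without LPS library 2. The sample weights were 7.70 for ultrasound library 1 and 0.362 for LPS library 2, and 8 of the 13 genes past the threshold with the block were among the 223 weighted ones. The 10 called gene lists became 0 with camera under an estimated correlation, 0 with fry for a shared direction and 2 with fry for either direction. With the replicate block the 10 lists were called by camera again and 0 under an estimated correlation. Of all 26 lists, fry with the block called 4 for a shared direction, the interferon and cell cycle lists and, outside the 10, the inflammasome and LXR lists. Leaving out 1 library gave 5 to 11 called lists, 5 of them without LPS library 2 and 6 without ultrasound library 1. The cause of these differences was not tested. The cholesterol list was not called with quantile normalization or sample weights. The NF-kB list was called with quantile normalization, without the filter and with the stricter one, the antigen presentation list with quantile normalization and without the filter, and the phagocytic list without the filter. The block changed no call other than those given here, beside the results and for the symbol families.

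The lowest correlation between libraries moved from 0.962 to 0.951 with pseudocount 0.1 and 0.946 with the stricter filter. Of 54 tested named genes, 53 kept their sign under every alternative, and the log2 fold change of Nos2, 0.10 with all libraries, turned to -0.011 without LPS replicate 3, within a range of -0.011 to 0.21 over the libraries left out, and never passed the threshold there. The count-based alternative was not run because the table holds no counts. Depth is not known from the table, so what it limits could not be set. In the simulated data, with 200 genes changed, 48% of 1.5-fold changes were recovered with 3 libraries per group. With fewer changed genes that share can be lower.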

Other observations

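The tests of the libraries numbered 2, whose form was changed more than once after values were seen, the scaling, the mitochondrial genes and the Krcc1 region were chosen after the results were seen, and those of GC content and length, of other splits and of a shared axis before. Among symbol families, a grouping of the tested genes by shared symbol stem that was chosen after the data were seen, 1 of 48 Rpl genes, of the large ribosomal subunit, was higher, with a median log2 fold change of -0.12 (camera with Benjamini-Hochberg adjustment over 110 families, p = 0.015, and adjusted p = 0.90 with an estimated correlation). The Rps family, of the small subunit, was higher in 7 of 42 genes with a median of -0.06 and was not called (camera with Benjamini-Hochberg adjusted p = 0.61). The Atp family, which holds ATPase and ATP synthase subunit genes, was higher in 39 of 55 genes with a median of 0.08 (camera with Benjamini-Hochberg adjusted p = 0.032, and adjusted p = 0.90 with an estimated correlation), and its call ended with the replicate block (camera with Benjamini-Hochberg adjusted p = 0.054). The Snhg family of small nucleolar RNA host genes was higher in 2 of 10 genes with a median of -0.39 (camera with Benjamini-Hochberg adjusted p = 0.038, and adjusted p = 0.90 with an estimated correlation), and its call ended with the block as well (camera with Benjamini-Hochberg adjusted p = 0.24).

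The cytokine, chemokine, interferon and effector lists together held 61 tested genes, of which 51 were lower with ultrasound in all 3 same-numbered pairs, with pair medians of -0.36, -0.56 and -0.37 and a median of -0.38 without pair 2. Bootstrap intervals here resample the genes of a list with the libraries held fixed, so they do not measure the spread between libraries. Without pair 2, which holds LPS library 2 and its high ultrasound partner, the cytokine median was -0.46 (bootstrap interval -0.71 to -0.34). The interferon median was -0.34 (-0.49 to -0.24) there. Both lists were thus also lower among the libraries outside pair 2, which argues against LPS library 2 alone as their cause in these libraries. Without pair 2 the chemokine median was also negative, at -0.26 (-0.82 to -0.08), and so was the effector median, at -0.25 (-0.49 to -0.03). LPS library 2 is absent there, so it alone does not give these values. The intervals of these lists reach above -0.1, a bound set after values were seen. How much of their fall rests on that library therefore stays open. Leaving out LPS library 2 alone gave -0.47, -0.16, -0.18 and -0.019 for the cytokine, interferon, chemokine and effector lists. The interferon median was -0.42 with all libraries. Scaling of the libraries left the median of the 61 genes at -0.43 (-0.59 to -0.33), and removing the trend with GC content and transcript length left it at -0.42 (-0.55 to -0.30). The median-ratio factors ran only from 0.979 to 1.015, so that scaling could move the median little. The tables argue against both as the whole cause in these libraries. An effect of ultrasound and of handling during the exposure remain open, since the labels name no sham exposure.

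For 1 shared rise of all mitochondrial RNA, 3 of the 13 genes, mt-Co1, mt-Nd5 and mt-Nd6, had a 95% interval wholly below the list median of 0.82. That number was set as the bound after these values were known, so passing it decides nothing. The genes did not all move equally: the 95% interval was -0.43 to 0.06 for mt-Co1 and 1.08 to 1.79 for mt-Co2. With the values of nuclear copies added, the median of the genes with copies was 0.58 (bootstrap interval over these genes 0.37 to 1.43). This argues against reads moving between them as the whole cause for these genes, and does not cover the genes without copies. The gene mt-Atp6 did differ: LPS library 2 had 149 FPKM of it and 930 of its copy Gm10925, against 1034 and 1098 in LPS library 1. Its log2 fold change was 1.04 with the copy added in place of 1.64, a value that rests on LPS library 2 and was 0.70 without it. The lower of the list medians without LPS library 2 and without pair 2 was 0.61, which argues against that library as the whole cause. The share of the FPKM sum from mitochondrial genes was 7.77%, 6.40% and 9.02% with LPS and 9.06%, 9.24% and 9.63% with ultrasound. RNA handling and a response of the cells remain open and were not tested.

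Krcc1 and Mir8112 were both higher and share sequence, and how reads were divided between them was not tested. The 7 tested neighbours within 500 kb had a median of 0.036 (range -0.24 to 0.19), which argues against a change of the whole region. The longest of 4 annotated Krcc1 transcripts is 4.19 times the length of the shortest and the fold change was 3.68, so assignment of the same reads to isoforms of another length cannot be told apart from more Krcc1 RNA.

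The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. As many genes past the threshold as the real 2 were found in 4 of the 10 splits, the highest of the other splits also giving 2. As many called lists as the real 10 were found in 4 of them, the highest other giving 10. For an unadjusted p below 0.05, 1 split, the real one, gave 1729 genes, and the highest other, LPS libraries 1 and 2 with ultrasound library 2, gave 1678. The other splits that part all 3 pairs gave 131, 101 and 148 such genes and 10, 0 and 4 called lists.

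A hypothesis is that the libraries numbered 2 and the ultrasound difference lie along one axis of inflammatory state, in opposite directions. It was tested with libraries not shared between the 2 measures, across the 11270 tested genes, which are not independent. The difference between libraries numbered 2 and 3 correlated with the ultrasound difference in pair 1 at -0.24, and that between libraries 2 and 1 with the difference in pair 3 at -0.28. Both lie below the bound of -0.1 set beforehand, as the hypothesis predicts. Both use the libraries numbered 2, so they are not independent of each other. The difference between libraries 1 and 3 gave 0.12 against pair 2, which shows how far such a correlation can lie from 0 where no axis was proposed. That is farther from 0 than the bound, so passing the bound does not settle the hypothesis. Taken across all tested genes, the correlations do not by themselves tie an axis to inflammatory state. Across the 61 members of the inflammatory lists they were -0.65 for pair 1 and -0.59 for pair 3. No value like the 0.12 was computed for these members, so these correlations do not settle the hypothesis either.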
